A study of Mus musculus with 16 samples.

How the data were processed

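The samples were 16 hybridizations of tail DNA from 8 mice of 1 family on Agilent arrays with 966371 spots besides controls, each against DNA of the male called reference mouse 5. The sire, the dam and each of 6 progeny had 1 array with the mouse in Cy3 and 1 with the mouse in Cy5, per the labels. Groups were the sire (1 mouse), the dam (1 mouse) and the progeny (6 mice), and the mean of the 2 arrays of a mouse was 1 replicate.

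Images were read on scanner model G2505C and quantified with Feature Extraction 10.7.1.1 under protocol CGH_107_Sep09, per the file headers, on probe positions of build mm9. Per the file headers, the deposited log10 ratio of a spot is log10 of red (Cy5) over green (Cy3) from signals that the software subtracted for background, detrended across the slide and scaled by 1 linear factor per dye, with no lowess step. The deposited intensity columns hold median spot and background brightness on a linear scale. The authors' value table holds log2 ratios, whose scale, centring and direction the sources used here do not state. Set against the scanner values of the same arrays, it correlated with log2 of red over green at 0.990 to 0.998 in size, differed from it, direction aside, by a median of 0.011 to 0.024 in size and ran as reference over mouse in 15 columns. The column of progeny 6 with the mouse in Cy5 had the opposite sign (r = 0.995, where the other 7 columns of that orientation lay between -0.998 and -0.994). Column medians lay between 0.013 and 0.017 with the mouse in Cy3, between -0.006 and -0.004 in those 7 columns, and at 0.017 in the odd column. Which further steps made that table is not given in the sources used here.

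From the log10 ratios, values were multiplied to the log2 scale, turned to mouse over reference by the dyes in the labels and centred on the median of the autosomal probes of each array. Spots with an outlier flag (133 to 493 per array) were left out, no spot was saturated, and spots of the same probe were averaged. No loess was applied. Between 98.7% and 99.8% of spots per array were well above background in both channels. The 2 turned arrays of a mouse correlated at -0.43 to -0.08 over all autosomal probes, while arrays of the same dye orientation from different mice correlated at 0.21 to 0.52. A probe-specific dye effect was therefore present on every array, which the mean of both orientations cancels where it is equal. The high X ratio of 5 mice against a male reference had the same sign on both arrays of each of them.

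Regions were called per mouse on the mean of its 2 arrays by an interval scan. An interval of 3 to 1000 probes scored the size of its summed log2 ratios over the robust SD times the square root of its probe number. The best interval was taken first, then its flanks. A call needed a score of 6 and a mean of at least 0.25 log2 in the same direction on each array. Calls of different mice in the same direction merged to a locus at 0.5 reciprocal overlap in probes. A mouse carried a locus when it was called there or when both its arrays passed 0.25 over the best call. Calls cover the 19 autosomes. The calling rule, the limma, binomial and window tests and the alternatives were fixed before the data were examined, except those named as added. The pairing test, the value without the strongest probe and the count of loci per set of mice were chosen after results were seen. Loci were named by rule: the 10 highest-scoring in progeny and in neither parent, the 10 highest in a parent and some progeny, up to 5 in all mice, the 3 highest in a parent alone, and up to 5 probes each way from the limma tests. Locus values were ranked among 10000 random autosomal windows of the same probe number. Where the scan of the same mouse picked the interval, this rank describes its size and tests nothing.

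Probe tests used limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on the mean per mouse, over probes measured on every array, with Benjamini-Hochberg adjustment at 0.05. The progeny mean was set against 0, and the progeny against the parents. The latter was repeated over all 28 choices of 2 of the 8 mice. Scan day as a random block used duplicateCorrelation with statmod 1.5.0 on 10000 probes. Scans and permutations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0.

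The scan was tested on simulated data by adding shifts of known size to both arrays of each mouse. At -0.5 log2 it recovered 43.8% of intervals of 3 probes, 86.2% of 5 probes, 98.8% of 10 probes and 100.0% of 20 probes. At -1 log2 it recovered 100.0% at each of these lengths. The limma test of the progeny against the reference was run on 100000 simulated probes with the spread of these progeny. It recovered 89% of 100 probes shifted by 0.5 log2 and 97% of 100 shifted by 1. Both sets were in 1 simulation, with 11 false calls beside them. The test against the parents recovered 23% and 74%, with 0 false calls.

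Alternatives were other thresholds of score, probe number and log2 ratio, the mean of the arrays alone, a 3-state hidden Markov model (state means at 0.5 log2, probability 1e-05 of leaving the middle state and 0.01 of returning), normexp background correction of the median signals with offset 50, the value table, removal of a long running median, all probes kept, probes left out that were not well above background in both channels on every array, merging at any shared probe, 1 dye orientation, scan day as a block, and leaving out each progeny. The plan named mean signals for normexp, for which medians were used, and set no values for the Markov model. Alternatives added after seeing the data were the pairing test without each mouse, a minimum of 10 probes, a rule on the median of the probes in each array, and the value table with its odd column as it stands.

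No correction for GC content was made, since no mm9 sequence was used here, and the running median stood in for it. The gene table given with the data is on GRCm38, and coordinates were not converted between builds, so no gene is named at a locus. The test of gene lists fixed beforehand (antigen receptor loci, multigene families, C57BL/6 substrain variants and DNA repair genes) was not run for the same reason. Precision is limited by the number of arrays, and p-values over progeny measure the spread among siblings of 1 family.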

Results

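The data are array comparative genomic hybridizations of tail DNA from 8 C57BL/6 mice of 1 family, a sire, a dam and 6 progeny, each set against the DNA of 1 reference male. In this assay, sample DNA and reference DNA carry different dyes and compete for the same probes, so that the ratio of the dyes at a probe gives the relative number of copies of that sequence. Each mouse was measured on 2 arrays with the dyes exchanged, 16 arrays in all, and the pair was counted as 1 replicate. The arrays held 950749 distinct probes with positions on mouse build mm9, of which 950622 were autosomal, at a median distance of 2053 bp. The labels are not settled on exposure. The series title describes males exposed to gamma rays at 0.05 mGy per day for 400 days and the family code carries that dose, while the design text calls the sire of this family non-irradiated. With 1 family there was no comparison of exposed with unexposed mice, and no result here bears on the dose.

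Copy number differences between the mice and the reference male are given as log2 of mouse over reference, the mean of both dye orientations. The noise of an array, the robust SD of differences between neighbouring probes, lay between 0.21 and 0.31 log2, and that of a mouse's mean of 2 arrays between 0.11 in progeny 2 and 0.18 in progeny 4. Signal to noise lay between 19.1 and 38.8 in the green channel and between 27.4 and 40 in the red channel. The number of arrays limits the precision of every value, and no value of a single mouse has a biological replicate.

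The few X and Y probes gave the size of a known difference. Over 68 X probes the dam and progeny 3, 4, 5 and 6 lay between 0.87 and 0.93 log2 above the reference male, and over 23 Y probes the same 5 mice lay between -1.90 and -1.69. The sire and progeny 1 and 2 lay between -0.01 and 0.01 on X and between 0.00 and 0.10 on Y. A doubling thus read as slightly less than 1 log2 unit, though with normexp background correction the X mean of the dam was 0.50 in place of 0.87. No whole autosome was shifted in any mouse, the chromosome means lying between -0.004 and 0.011 log2.

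The clearest copy number difference of the family was a gain on chromosome 4, from 101110482 to 101270535 (160054 bp, 74 probes). It was carried by the sire and all 6 progeny and not by the dam. The sire read 0.95 log2, a ratio of 1.93, in which the Cy3 orientation gave 0.97 and the Cy5 orientation 0.93. All 6 progeny read an intermediate 0.54 ± 0.005 (SD, n = 6), a ratio of 1.46, and the dam read 0.02. None of 10000 random autosomal windows of 74 probes read as high in the sire or in any of the 6 progeny. In the dam, 2935 windows did. This locus falls outside the rule that fixed which loci are named and was chosen after its values were seen.

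**Figure D1:**
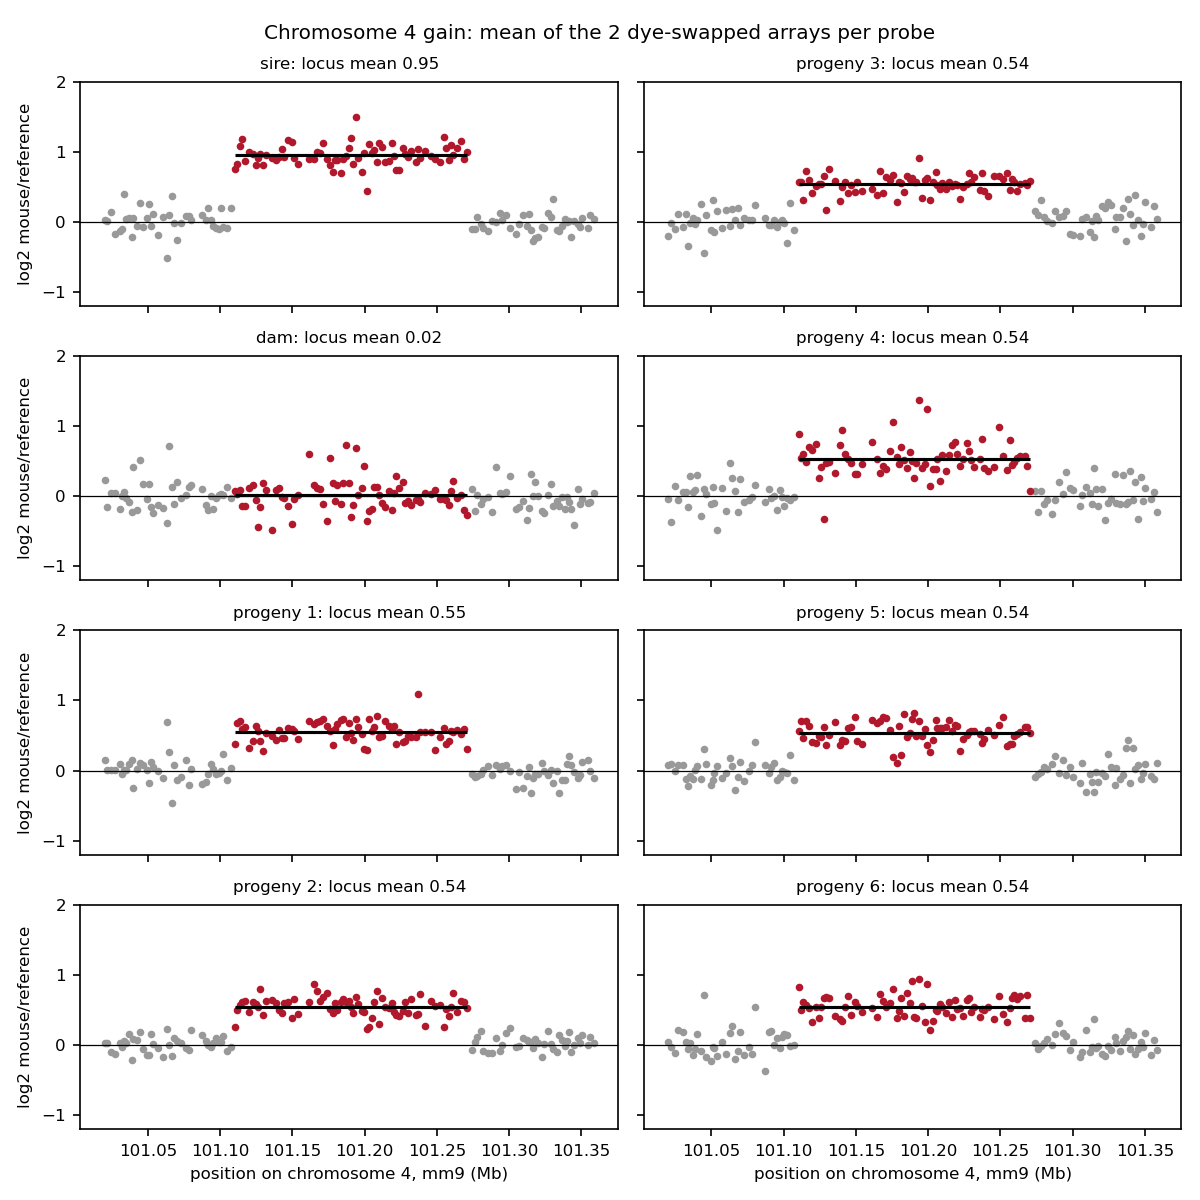
Log2 of mouse over reference (y axis) at each probe by position in Mb on chromosome 4 (x axis), 1 panel per mouse, each point the mean of 2 dye-swapped arrays. Red points are the 74 probes of the locus, grey points flanking probes and the black bar the locus mean, which is 0.95 in the sire, 0.54 to 0.55 in the progeny and 0.02 in the dam.

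The same region dominated the test of the progeny against the reference. Using limma with Benjamini-Hochberg adjustment, 60 of 949352 probes differed between the 6 progeny and the reference male, 58 higher and 2 lower. All 58 higher probes lay in the chromosome 4 locus, where all 74 probes had a positive mean, from 0.24 to 0.89 log2. The largest mean, 0.89 (SE 0.08, limma adjusted p = 0.0056, higher in 6 of 6 progeny), was at probe A_67_P00943900, where the dam also read 0.69. The next were A_67_P00943889 at 0.68, A_67_P00943841 at 0.66, A_67_P05336948 at 0.64 and A_67_P05336758 at 0.64. The 2 lower probes both lay on chromosome 11. A_67_P07484457 at 108078704 read -0.52 (SE 0.06, limma adjusted p = 0.037, lower in 6 of 6 progeny) and A_67_P02398071 at 93714525 read -0.45 (SE 0.05, limma adjusted p = 0.039, lower in 6 of 6 progeny). The sire and the dam were below 0 at both, at -0.56 and -0.33 for the former probe and at -0.37 and -0.49 for the latter. The reference is 1 animal whose own spread is not in the test, and the 6 progeny are siblings. With 1 dye orientation alone the count was 138416 (Cy3) or 158119 (Cy5). It fell to 34 without progeny 1, 39 without progeny 2 and 37 without progeny 3. Both lower probes were lost without progeny 3, 4 or 6, where 0 lower probes passed, and 1 passed without progeny 1.

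The question of the series is whether progeny carry copy number changes that neither parent carries. The highest-scoring such locus was a loss on chromosome 14 in progeny 4, from 60132704 to 60151750 (19047 bp, 11 probes). Progeny 4 read -0.85 log2, a ratio of 0.55, with -0.83 in the Cy3 orientation and -0.87 in the Cy5 orientation. All 11 probes were below 0, and the value was -0.81 without the strongest of them. None of 10000 random windows of 11 probes read as low in progeny 4. The other 5 progeny lay between -0.04 and -0.01 and the sire at -0.03. The dam read -0.16, below the threshold for a carrier, with all 11 probes below 0. Of 10000 windows in the dam, 34 read as low. Over the 15 probes before the locus the dam read -0.07 and progeny 4 0.08, and over the 15 probes after it 0.02 and 0.03. The 3 probes next to its start were above 0 in the dam, and the 12 before them averaged -0.12. With normexp progeny 4 read -0.52.

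**Figure D2:**
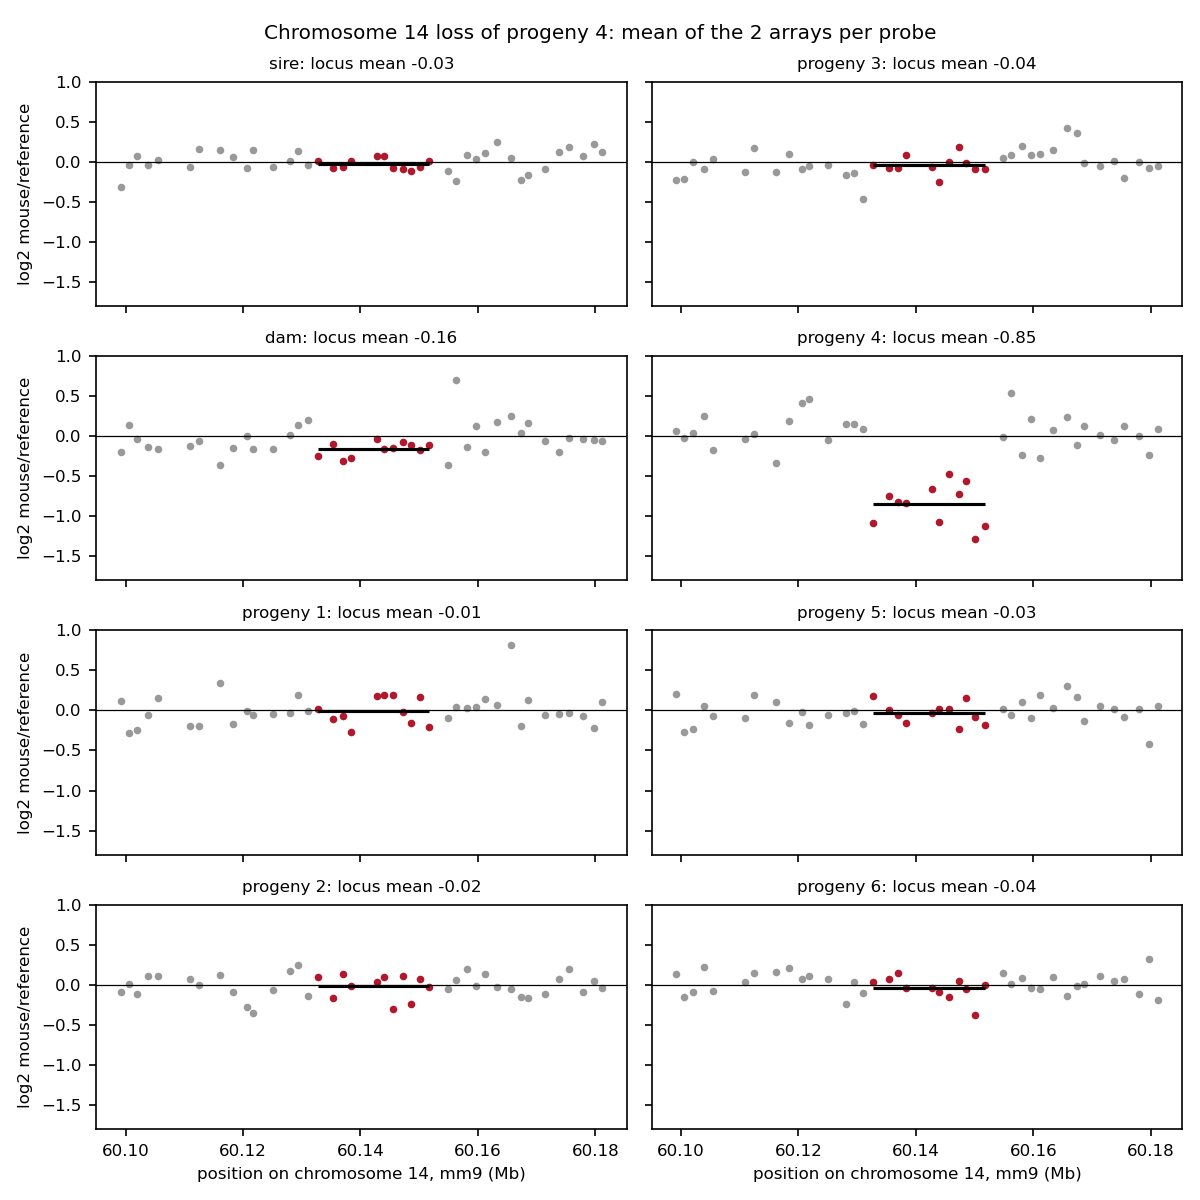
Log2 of mouse over reference (y axis) by position in Mb on chromosome 14 (x axis), 1 panel per mouse, each point the mean of 2 dye-swapped arrays. Red points are the 11 probes of the locus and the black bar their mean, -0.85 in progeny 4 and -0.16 in the dam, against -0.04 to -0.01 in the other 6 mice.

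Across the 8 mice the calling rule gave 664 regions, which merged to 585 loci, 279 gains and 306 losses. Most were very short: 552 loci spanned 3 or 4 probes and 9 spanned 10 or more. Calls per mouse were 69 in the sire, 95 in the dam and 83, 41, 66, 46, 66 and 198 in progeny 1 to 6. No locus was shifted in all 8 mice, 389 loci were called in progeny and in neither parent, and 131 were carried only by parents. Of the 389 progeny loci, 346 were carried by a single progeny, and progeny 6 carried 187 of the 389. Without progeny 6 the 389 fell to 223. The high count of progeny 6 followed its Cy5 array. Scanned with the Cy3 arrays of other mice, that array gave 118 to 195 calls of 3 to 4 probes. The Cy3 array of progeny 6 gave 27 to 81 with the Cy5 arrays of other mice. These 2 arrays also had the most flagged spots, 350 and 493.

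The short calls were not shown to be tied to the mouse. When the Cy3 array of a mouse was scanned with the Cy5 array of a different mouse, the 56 such pairs gave a mean of 73.3 calls, against 83.0 for the 8 pairs of the same mouse. In an exact one-sided permutation test over all 40320 pairings of the arrays, 2183 pairings reached the same-mouse total of 664 calls (p = 0.054). Leaving out a mouse moved this exact p to 0.038 without the sire, 0.029 without the dam and 0.015 without progeny 3, and to 0.059 to 0.203 without any of the others. Pairs of different mice hold signals that family members share, so their calls are not a level of noise alone. For calls of 3 to 4 probes the same-mouse total was 617, against a median of 557 over the pairings (exact one-sided permutation p = 0.077). For calls of 5 to 9 probes it was 25 against 22 (exact one-sided permutation p = 0.32). For calls of 10 or more probes the same-mouse total was 22, against a median of 14 over the pairings, and 98 pairings reached it (exact one-sided permutation p = 0.0024). Progeny 4 gave 8 of the 22, and without it the total was 14 against a median of 10 (exact permutation p = 0.018). In 389 of the 585 loci, 66.5%, the mean of the best mouse fell below 0.25 log2 once its strongest probe was left out, as it did in 0 of the 9 loci of 10 or more probes.

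**Figure D3:**
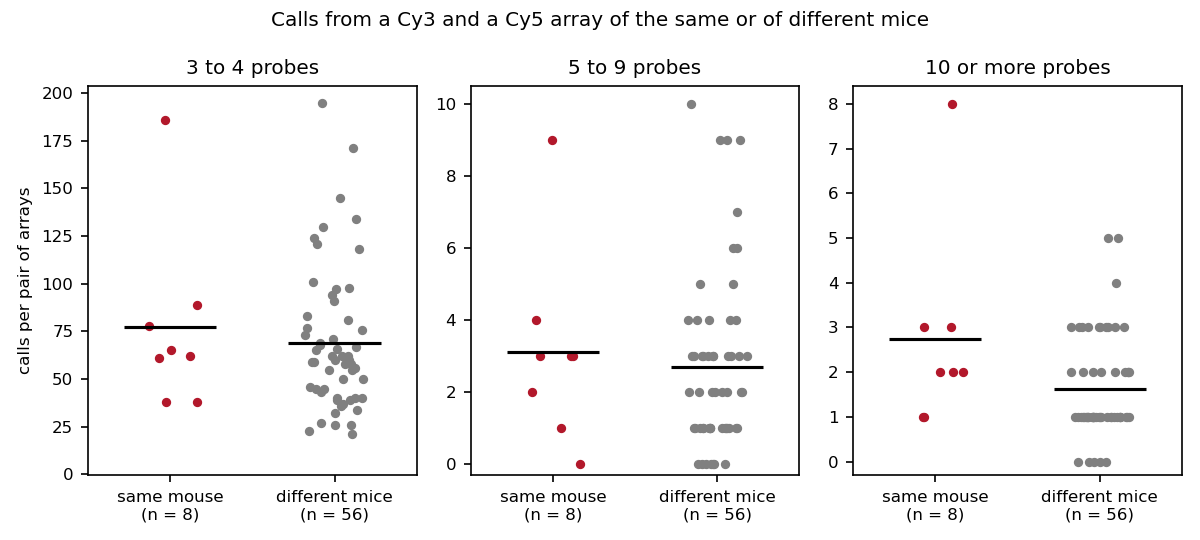
Calls per pair of arrays (y axis) for a Cy3 and a Cy5 array of the same mouse (red, n = 8) or of different mice (grey, n = 56), in 3 panels by the number of probes in the call. Black bars are means, 77.1 against 68.9 for 3 to 4 probes, 3.12 against 2.70 for 5 to 9 and 2.75 against 1.62 for 10 or more.

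Of the 389 loci in progeny alone, 4 spanned 10 or more probes, all with their highest score in progeny 4. Besides the loss on chromosome 14 these were gains on chromosome 17 from 3006536 to 3031159 (12 probes, 0.44 log2), chromosome 3 from 3007472 to 3028641 (10 probes, 0.40) and chromosome 7 from 71215712 to 71232393 (10 probes, 0.39), which were named after their values were seen. The dam read 0.26, 0.20 and 0.26 there, with both arrays above 0. Of 10000 random windows of the same probe number, 0, 27 and 5 read as high in the dam. It was no carrier by the rule, since its Cy3 orientation read 0.19, 0.19 and 0.24, below the threshold of 0.25. Its Cy5 orientation read 0.33, 0.21 and 0.28. These gains were therefore not shown to be absent from the dam. Progeny 6 read 0.34, 0.28 and 0.20. Progeny 6 was high in the Cy3 orientation alone, at 0.62, 0.56 and 0.43 against 0.05, 0.01 and -0.04 in the Cy5 orientation. The gains on chromosomes 17 and 3 began at probe 2 and probe 4 from the chromosome start, and how reliable ratios are there was not tested.

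The remaining named loci of progeny alone were of this short kind. All 9 spanned 3 probes, 7 losses and 2 gains, with values from -1.21 to 0.86 log2 in the mouse with the highest score, and 5 of them had it in progeny 6. Their arrays differed by 0.16 to 1.82 log2 between the orientations. At 5 of the 9 the value fell below 0.25 in size without the strongest probe. An example is chromosome 6 from 148606317 to 148611340 in progeny 4, where -1.21 went to -0.05. The orientations were closest at a loss on chromosome 8 from 107155548 to 107159737 in progeny 6, at -1.14 log2 with -1.06 and -1.22 in the orientations and -0.90 without its strongest probe. Progeny 4 also carried it, at -0.54, while the parents read 0.08 and 0.07. The value in progeny 6 was -0.33 once dim probes were left out and -0.09 with normexp. The loss on chromosome 3 from 152016014 to 152019033 in progeny 6 kept -0.70 of its -0.94 with normexp, with -0.25 and -1.63 in the orientations and -0.28 without its strongest probe. The 2 gains were on chromosome 2 from 70082725 to 70085630 in progeny 2, at 0.82, and on chromosome 15 from 39774254 to 39777817 in progeny 5, at 0.86. The former read 1.32 and 0.32 in the orientations and -0.01 with normexp. Progeny 1 also carried it, at 0.70, progeny 4 read 0.39, and the sire read 0.34 with both arrays above 0, a level that 2 of 10000 windows of the sire reached. The latter read 0.59 and 1.13, and 0.11 with normexp or 0.24 with dim probes left out.

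Loci carried by a parent and by some but not all progeny numbered 64, 24 gains and 40 losses. The highest-scoring was a shallow loss on chromosome 14 from 53430657 to 54358210 (927554 bp, 96 probes) in the dam, progeny 2 and progeny 4. The dam read -0.28, progeny 2 -0.32 and progeny 4 -0.30 log2, ratios of 0.82, 0.80 and 0.81. The 2 arrays of each of these mice differed by at most 0.03. The other 5 mice lay between -0.02 and 0.04. The highest of these, progeny 5, was raised by 1 probe at 54084604 that read 5.84. None of 10000 random windows of 96 probes read as low in any of the 3 mice. The loss was uneven along the interval: over the 37 probes at its start the 3 mice read -0.32, -0.33 and -0.34, over the next 15 probes, from 53610045 on, -0.49, -0.53 and -0.47, and over the last 44 probes -0.19, -0.23 and -0.21.

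**Figure D4:**
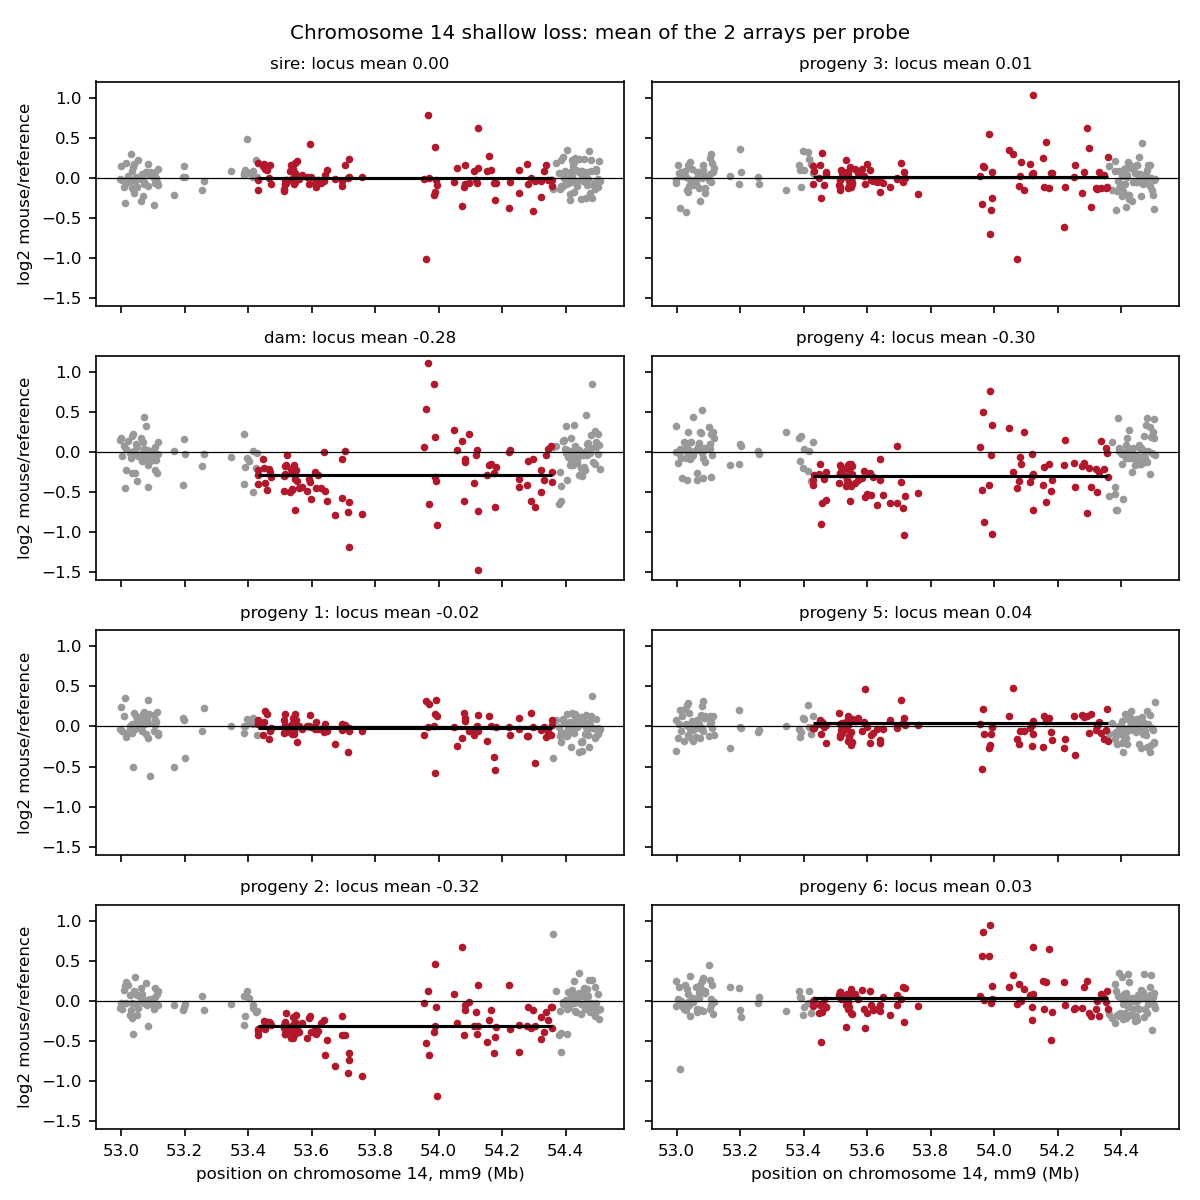
Log2 of mouse over reference (y axis) by position in Mb on chromosome 14 (x axis), 1 panel per mouse, each point the mean of 2 dye-swapped arrays. Red points are the 96 probes of the locus and the black bar their mean, between -0.32 and -0.28 in the dam, progeny 2 and progeny 4 and between -0.02 and 0.04 in the other 5 mice. A probe of progeny 5 at 5.84 lies above the plotted range and is part of its mean.

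A single set of mice recurred among these 64 loci. The dam and progeny 3, 4, 5 and 6 together, the 5 mice with the high X ratio, carried 25 loci on 14 chromosomes, and 7 of the 10 named loci were among them. Of the 25, 24 were losses of 3 to 4 probes. Their mean over the 5 mice reached -1.50 log2 at chromosome 3 from 25417435 to 25444229 (4 probes), where the dam read -1.48 and the 4 progeny -1.44, -1.54, -1.55 and -1.47. Others were at chromosome 6 from 104241394 to 104246570 (mean -1.37) and from 104236953 to 104241453 (mean -1.32), chromosome 16 from 40849337 to 40854519 (mean -1.02), chromosome 7 from 141017667 to 141020625 (mean -1.06) and chromosome 3 from 132549431 to 132553080 (mean -0.87). The only gain of the 25 was long, 46 probes on chromosome 8 from 102125282 to 102253497, at 0.24 in the dam and 0.28, 0.28, 0.29 and 0.29 in the 4 progeny. At the 4-probe locus of chromosome 3 all 4 probes were below 0 in each of the 5 mice. The other 5 named losses of this set rested on 1 probe each, and no value of these mice there lay outside -0.23 to 0.17 without it. Some neighbouring loci of the 25 share such a probe, so that the 25 are not all separate. The sire and progeny 1 and 2 averaged between -0.18 and 0.11 at each of the 25 loci, although the sire alone read -0.53 at chromosome 11 from 59716785 to 59721060.

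**Figure D5:**
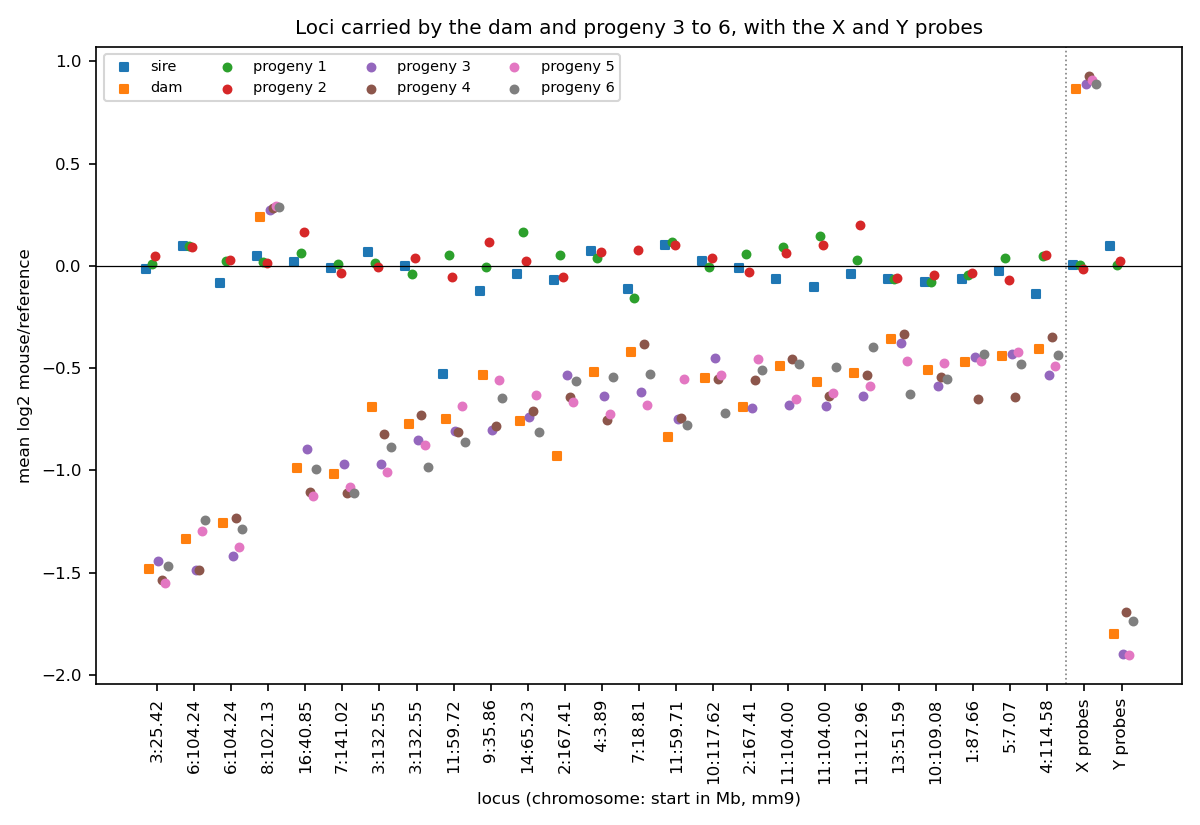
Mean log2 of mouse over reference (y axis) at the 25 loci carried by exactly the dam and progeny 3 to 6, named by chromosome and start in Mb (x axis), with the means of the X and Y probes at the right. Each point is 1 mouse (squares, parents), and the 5 carriers lie together at each locus while the mean of the other 3 mice stays between -0.18 and 0.11.

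Of the other named loci in this class, chromosome 11 from 76357341 to 76361590 was higher in both parents (0.53 and 0.55) and in progeny 6 (1.00), and read -0.68 in progeny 4 and -0.41 in progeny 2. The orientations of progeny 6 gave 1.53 and 0.47, and its value was 0.06 with normexp. Chromosome 13 from 95707465 to 95712034 was higher in both parents and in progeny 1 to 4, at 0.73 in progeny 2, of which 0.11 was left without the strongest probe. Transmission was tested at 58 loci with 1 carrier parent, the dam at 53 and the sire at 5, by an exact two-sided binomial test against 0.5. Of the 53, 25 were the loci of the dam and progeny 3 to 6, and 11 those of the dam and progeny 4 alone. The 53 and 5 are therefore not counts of loci shown to be inherited from each parent. The smallest p that 1 to 5 carriers among 6 progeny allow is 0.219, so no locus of this class could pass (lowest adjusted p = 0.453). For the chromosome 4 gain, with 6 of 6 carriers, the exact binomial p was 0.0313, without adjustment. Since that locus was taken for being carried by all progeny, this p was fixed in advance and tests nothing.

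The 3 named loci of a parent alone were losses of 3 probes in the sire. They lay on chromosome 3 from 37794836 to 37801593 (-0.96 log2) and on chromosome 11 from 121630458 to 121637216 (-0.84) and from 79898985 to 79903751 (-0.79). Without the strongest probe they read -0.09, -0.09 and -0.07.

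No single probe passed the test of progeny against parents. In limma, 0 of 949352 probes passed after Benjamini-Hochberg adjustment (lowest adjusted p = 0.22), and 41337 had an unadjusted p below 0.05. That is a smaller share of the probes than the 0.05 that chance alone gives. With the Cy3 orientation alone 1 probe passed. The parents were scanned on a day of their own and the progeny on 3 other days. With scan day as a random block the count of passing probes stayed at 0, with 54063 probes at an unadjusted p below 0.05, a share slightly above 0.05. Since no scan day held both generations, this comparison has no value within a day.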

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

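Of the tests in this part, the random windows and the removal of a running median were planned at the outset, though what the windows would show was written down after; the others were chosen after the results were seen.

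Among the 6 progeny, 54 measures were tested for a mouse far from the other 5, and 8 had one, where chance gives about 1 in 20. Progeny 6 had 198 calls, against 83 in the next mouse, and its Cy5 array gave high counts with the Cy3 arrays of other mice too. Progeny 4 had 8 calls of 10 or more probes, against 3 in the next. The chromosome 2 mean of progeny 2 was -0.0032, against 0.0001 in the next. The other 5 measures were loci called in progeny alone, which are picked for a mouse that stands apart: progeny 4 at chromosome 14 from 60132704 (-0.851) and chromosome 6 from 148606317 (-1.213), and progeny 6 at chromosome 8 from 91120931 (-1.051), chromosome 1 from 80897397 (-1.024) and chromosome 3 from 152016014 (-0.939). Without the strongest probe these 5 read -0.808, -0.046, 0.004, -0.2 and -0.283, in that order.

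The loss of progeny 4 on chromosome 14 from 60132704 to 60151750 had a weaker counterpart in the dam, at -0.16 log2 with all 11 probes below 0 (-0.07 over the 15 probes before the locus, of which the nearest 3 were above 0 and the other 12 averaged -0.12, and 0.02 over the 15 after it). Of random windows of the dam, 0.34% read as low. This value was singled out after it was seen, among those of both parents at the named loci of progeny alone. Its rank therefore does not decide about chance placement, nor does it set the locus apart from the 12 probes at -0.12. DNA of progeny 4 in the dam's sample would need a share of 23.6%, which predicts 0.146 at the chromosome 4 gain, where the dam read 0.016 (window SD 0.0232). A dye effect would turn its sign between the orientations and cancel in their mean, whereas the dam read -0.18 and -0.14 with a mean -2.73 window SD from 0, a criterion set after a first one, each orientation beyond 2 SD, was not met (the weaker lay at -1.34), and resting on the same value as the window rank. The dam and progeny 4 also moved together elsewhere, with 11 loci of these mice alone and 0.26, 0.20 and 0.26 in the dam at the other long loci of progeny 4, so what lowers the dam there stays open, and no biological explanation was tested.

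The loci of the dam and progeny 3 to 6 followed the mice with the high X ratio. Autosomal variants of the dam passed on independently would rarely give the same 4 of 6 progeny on 14 of 19 chromosomes (exact binomial p = 5.59e-22 at 1 in 64 per chromosome). This p gives each chromosome 1 try, though some held several loci. The set was also picked after it was seen as the most frequent in these data, so the p overstates how rare it is. Sequence shared between these probes and X or Y could give such a set, with losses where the reference male's Y adds signal and a gain where X does. At all 25 loci (100%) the 5 mice shared a level and the mean of the other 3 was near 0 (the sire alone read -0.53 at chromosome 11 from 59716785), but the rule that picks carriers nearly fixes this, so it does not decide. No sequence was compared.

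The shallow loss on chromosome 14 from 53430657 to 54358210 in the dam, progeny 2 and progeny 4 was not removed with a long-range wave, the mean of the 3 mice being -0.268 after the running median was taken off. The scan of progeny 2 set the interval and the dam its class, so their ranks test nothing, but progeny 4 was needed for neither, and 0 of 10000 random windows of it read as low, which argues against chance among windows of the same size. The weakest of the 6 arrays lay -6.0 window SD from 0, where a dye effect would turn the sign between the orientations. The rules for calls and carriers already required each array to pass a threshold in the same direction. The shared sign therefore cannot decide about a dye effect. The orientations differed by at most 0.03 in each mouse, a difference on which the rules set no limit. Because the gene table places the T cell receptor alpha and delta genes on chromosome 14, without a position on this build, a different share of rearranged lymphocyte DNA in the tail samples may be considered beside an inherited loss. Neither was tested.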

How the results depend on the processing

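Calls per mouse (83.0), loci in progeny alone (389) and loci of a parent and some progeny (64) depended on the thresholds; the cause was not tested beyond what each setting does by construction. In this order they were 20.12, 72 and 24 at a score of 8, 217.12, 1075 and 130 at a score of 5, 29.5, 123 and 30 with at least 5 probes, 44.5, 204 and 24 at 0.4 log2, 211.62, 974 and 206 on the mean of the arrays alone, 25.62, 114 and 25 with the hidden Markov model, and 34.88, 119 and 39 with dim probes left out. With normexp the first pair was 36.75 and 106. At 0.15 log2 loci of a parent and some progeny were 143. Added after seeing the data, at least 10 probes gave 7.12, 18 and 10, and the median rule 28.62, 137 and 26. Without 1 progeny, loci in progeny alone ranged from 223 (without progeny 6) to 365. Scans with a higher probe minimum stretch short signals to longer intervals, so their calls are not a subset.

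Probes differing between progeny and reference (60) were 138416 with Cy3 alone and 158119 with Cy5 alone, which the mean of both orientations is built to cancel, 0 with the odd column as it stands, and 34 to 53 without 1 progeny. Between progeny and parents 1 probe passed with Cy3 alone and 0 under the other alternatives. The progeny mean at the chromosome 4 gain (0.541) was 0.482 with normexp, 0.52 with the running median removed, 0.535 with dim probes left out and 0.448 with the odd column. The X mean of the dam (0.867) was 0.502 with normexp. Loci in all mice stayed at 0 under each alternative run. Signs turned for progeny 2 at chromosome 2 from 70082725 (-0.013 with normexp) and for progeny 6 at chromosome 8 from 91120931 (0.004 with dim probes left out); the cause was not tested. Of the other values at named loci, 18 moved and 118 did not. A value moved when it changed by more than the SD of that mouse's 2 arrays, so loci whose arrays disagree could hardly move. Normexp moved 10 and left 17, and leaving out dim probes moved 6 and left 19. The other settings moved at most 1 each. Of single-mouse call counts, 78 moved and 42 did not. The gene list test and its circular shift were not run. Signal to noise went down to 19.1 in the green channel, and how far it limits the values was not compared.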

Other observations

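The tests of the chromosome 4 gain and of the array pairings were chosen after related results were seen; the 28 choices of mice were planned at the outset, but what they would show was written down after.

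On chromosome 14 from 61798066 to 61819370 (13 probes), the dam read -0.29 log2 and progeny 3, 4, 5 and 6 read -0.25, -0.32, -0.29 and -0.35, against -0.02 in the sire and -0.01 in progeny 1 and 2. The mice with the low values are those with the high X ratio. Progeny 5 was no carrier by the rule, its Cy3 orientation reading -0.22, so the locus was not counted with the others of these mice. A gain on chromosome 3 from 26455377 to 26483864 (10 probes) read 0.35 in the dam and 0.17 in progeny 4.

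The sire read higher than the progeny at the chromosome 4 gain, by 0.407 log2, against an SD of 0.005 among the progeny. This argues against a gain on only 1 of the sire's homologues with the same copy number as in the progeny. A gain on both homologues, of which each progeny received 1, may be a candidate explanation, with 6 of 6 carriers as it requires; it was found and weighed on the same values.

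Calls of 3 or more probes were not shown to belong to the mouse: 2183 of the 40320 pairings of arrays had as many, the highest other total being 764, and leaving out the sire, the dam or progeny 3 took the exact permutation p from 0.0541 to 0.0377, 0.0292 or 0.0153. For calls of 10 or more probes 98 pairings had as many as the real 22, the highest other being 23 (without progeny 4, which gave 8, 90 of 5040 pairings reached 14), which argues against noise shared by dye orientation as the whole cause. Both arrays of a mouse were scanned on the same day, while the pairings mix days, so noise of a scan day was not set apart from the mouse.

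For progeny against parents, the real count was 0 probes, which all 28 splits into 2 and 6 mice reach whatever the data, so they test nothing here. The highest other choice gave 20 probes, with 148006 at an unadjusted p below 0.05, and set the dam and progeny 4 apart. So many more probes than in the real one point to some structure of the samples, whose nature was not tested. These mice had noise of 0.18 log2 each, and they alone shared 11 loci on 9 chromosomes.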
